A study of Mus musculus with 12 samples.

How the data were processed

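The series measured acetylation of histone H3 at lysine 27 (H3K27ac), a mark of active promoters and enhancers, by chromatin immunoprecipitation and sequencing of mouse liver. Per the labels' protocols, mice with a floxed Cox10 allele received an adeno-associated virus that carried either GFP or Cre recombinase, a 70% partial hepatectomy followed 4 weeks later, and the regenerating liver was taken on day 2. The 12 samples are 3 H3K27ac and 3 input libraries of each genotype. The 6 input libraries were not used here. The labels number the replicates but do not say that each came from its own animal. The p-values therefore rest on differences between libraries that may be technical.

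The table used holds normalised read counts per region (a signal) that the authors deposited. Each value equalled a whole number of reads divided by 1 size factor per library: 100% of values came out whole within 0.01 reads. Size factors were 0.752, 0.730 and 0.782 in wild type and 1.18, 1.24 and 1.32 in the knockout. Spike-in chromatin was added before immunoprecipitation per the labels' protocols, and how the size factors were obtained is not given in the sources used here. The build is mm10, and BWA 0.7.5, MACS and deepTools 3.5.0 are named, without roles, per the submitters' processing notes. The authors deposited log2 fold changes, p-values and adjusted p-values for knockout over wild type in the same table, together with the annotation of each region. Coordinates are given as in that table, whose counting base is not stated. A region away from promoters carries the name of its nearest gene, which need not be the gene it acts on. Of 36446 regions listed, 59 repeated another and were dropped, which left 36387 regions with 11240 gene names on 18 autosomes and the X chromosome. Chromosome 16 was not analysed here.

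Regions were tested with limma 3.58.1 in R 4.3.3 on log2(value + 1), with a trend of variance on mean level, no filter and no block, between 3 libraries per genotype, and Benjamini-Hochberg adjusted p under 0.05 was the threshold. A pseudocount understates the change of low regions. Limma draws the variance of each region towards a trend over all regions. The SE and p of a region are therefore not those of its own libraries alone. Regions within 1 kb of a start site, by the deposited annotation, were called promoters, and classes were compared with Fisher's exact test, two-sided, which is a test across regions and not across animals. For each of 32 gene lists, written before the data were examined, camera with a preset correlation of 0.01 compared the members with all other genes. Each gene was represented by its promoter region of highest mean signal, or by the mean over all regions assigned to it. Lists needed at least 3 measured members. Of 848 list genes, 639 had a region, 2 of them through an older symbol.

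The lists were tested on values centred on the median level over genes in each library. This scale was chosen after the data were examined, and after the lists had first been tested on the deposited scale, where 11 lists were lower and 3 higher at promoters. In 20 simulations of 9663 promoter genes in 3 against 3 libraries, a common shift of -1 was set on the log2 scale. Against this shift 60 lists were moved upward by 0.5. No list was moved downward, so the recovery of lower lists was not simulated. Centred values recovered 60 of the 60 and called 1 of 482 lists that had not been moved. With the common shift kept, 59 of 60 were recovered and 199 of the 482 other lists (41.3%) were called. Why they were called was not tested. In the simulations every gene outside the moved lists had the same change, and genes were drawn independently. Real genes differ in their change and may vary together, so these shares do not give the rate of false list calls in the data. Counts on both scales are given. Camera with an estimated correlation, and fry on centred values, were run beside it.

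The region test was tested on simulated data for 36387 regions in 3 against 3 libraries. It recovered 14% of regions changed 1.25-fold, 54% at 1.5-fold, 82% at 2-fold and 100% at 4-fold, and 3.85% of its calls were unchanged regions. The simulation changed 50 regions at each fold size and had no common shift. In the data most regions were called, which loosens the adjusted threshold, so these shares do not describe the comparison of genotypes. The genes named were set by a rule written before the data were examined. It takes the 6 regions per direction with the largest fold change past the threshold and a mean signal at or above the median, 1 per gene and without predicted gene names. It also takes up to 2 members per direction of each list, by the smallest adjusted p at the promoter, and Cox10. Alternatives were another pseudocount, other thresholds, a block, leaving out each library, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, and other scalings.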

Results

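H3K27ac was measured in regenerating mouse liver with and without Cox10, which encodes an enzyme of heme A synthesis needed to assemble cytochrome c oxidase. Each genotype had 3 H3K27ac libraries. The regions held 4138459, 3897454 and 4187377 reads in the wild-type libraries and 3302556, 3385453 and 3282878 in the knockout libraries. Pairs of libraries of a genotype differed by little more than sampling noise, with a chi-square per degree of freedom of 1.16 to 1.19 in wild type and 1.06 to 1.11 in the knockout, against 10.2 to 10.6 between genotypes. In a chi-square test that treats reads as independent molecules, every pair of a genotype differed (highest p = 1.0e-16), which does not show that the libraries came from separate animals. The 3 libraries per genotype were counted as the labels give them.

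Cox10 itself carried 1 region, on chromosome 11 from 63977336 to 63977787 (mm10), in intron 5 of 6 of its transcript. This region held 15.1 ± 2.54 normalised reads in wild type and 57.4 ± 10.3 in the knockout (SD, n = 3). It was 3.62-fold higher in the knockout (log2 1.86, SE 0.24, limma adjusted p = 2.0e-12). The labels do not say which exon is floxed, and an acetylated region in an intron does not check the deletion.

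Loss of Cox10 was compared with wild type to ask where H3K27ac differed in the regenerating liver. On the deposited scale, H3K27ac was lower in the knockout at 31719 of 36387 regions and higher at 1622 (limma, adjusted p under 0.05). Among regions with a mean signal at or above the median, 17132 were lower and 285 higher, so most rises lay at weaker regions. The median region of all was 2.06-fold lower (log2 -1.04, interquartile range -1.58 to -0.64). The sum of normalised reads was 5398383 ± 92961 in wild type and 2675320 ± 167095 in the knockout (SD, n = 3), 50.4% lower, with an exact permutation p of 0.1, two-sided, the smallest that 3 against 3 libraries allow. The authors' deposited table gives 30858 regions lower and 1301 higher at the same threshold. The balance depends on the scale: with each library centred on its median region, a shift of 1.05, 11800 regions were lower and 12224 higher.

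Among regions with a mean signal at or above the median, the largest rise lay at the promoter of Zfand2a, a heat-shock and arsenite inducible gene, on chromosome 5 from 139479414 to 139480334. It rose from 20.7 ± 5.26 to 163.2 ± 5.32 normalised reads (SD, n = 3), 7.69-fold (log2 2.94, SE 0.17, limma adjusted p = 3.5e-41). A region in intron 6 of 9 of the long noncoding RNA gene Pvt1, on chromosome 15 from 62334601 to 62336048, was 6.42-fold higher (log2 2.68, SE 0.14). Near Pdk4, which encodes a kinase that inhibits pyruvate dehydrogenase, a region 2 to 3 kb from the start site was 5.18-fold higher (log2 2.37, SE 0.14). Regions nearest to Nln, Arhgef2 and Dlgap1 were 4.95-fold, 4.79-fold and 3.82-fold higher.

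Among the same regions, the deepest falls were near Grid1 and Ctnnd2. The Grid1 region, in intron 4 of 15 on chromosome 14 from 35119598 to 35120164, went from 152.5 ± 7.21 to 4.53 ± 2.44 normalised reads (SD, n = 3), 29.5-fold lower (log2 -4.88, SE 0.26, limma adjusted p = 2.3e-46). An intergenic region nearest to Ctnnd2, on chromosome 15 from 31062519 to 31063716, was 25.8-fold lower (log2 -4.69, SE 0.17). Regions nearest to Ubl7 and Apba2 were 16.2-fold and 13.1-fold lower. An intergenic region nearest to the pseudogene Mup-ps21 and a promoter region of Serpina1b, an alpha-1-antitrypsin gene, were 17.6-fold and 15.7-fold lower. Reads of the Mup and Serpina1 genes may be shared between near-identical copies. All 12 of these regions kept their direction when each library was centred on its median region.

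**Figure D1:**
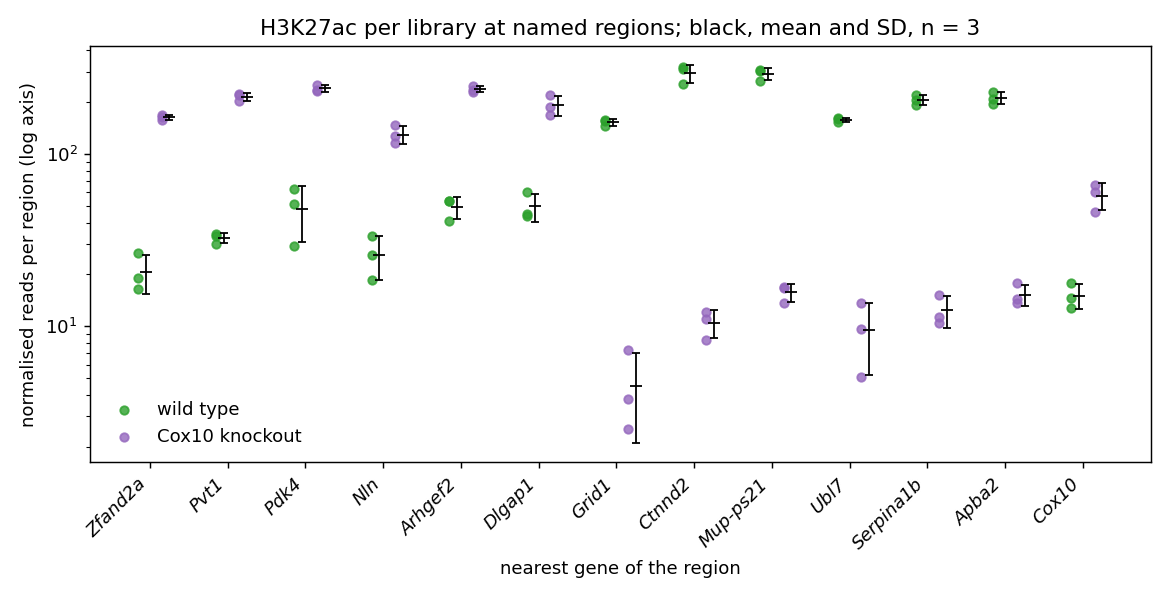
Normalised reads per library (log axis) at the named regions and the Cox10 region, labelled by nearest gene, with wild-type libraries in green, knockout libraries in purple, and black marks for the mean and SD of 3 libraries. At Zfand2a the mean was 20.7 in wild type and 163.2 in the knockout, and at Grid1 152.5 and 4.53.

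Promoters and other regions were compared because H3K27ac marks both promoters and enhancers. Regions away from promoters fell further: their median was 2.43-fold lower (log2 -1.28, 20407 regions), against 1.82-fold lower at promoters (log2 -0.87, 15980 regions). Regions away from promoters also held most of the rises, with 1420 of them higher (6.96%) against 202 at promoters (1.26%). At promoters 92.3% of regions were lower, against 83.2% elsewhere. The odds ratio of a promoter over other regions was 2.43 for lower calls (Fisher's exact test across regions, p = 2.6e-154) and 0.171 for higher calls (p = 1.3e-172). With centred libraries both ratios turned, to 0.307 and 1.98. The SD of log2 fold changes was 0.592 at promoters and 0.992 elsewhere. The median level at promoters exceeded that elsewhere by 0.733 ± 0.023 (log2) in wild type and 0.970 ± 0.0096 in the knockout (SD, n = 3).

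**Figure D2:**
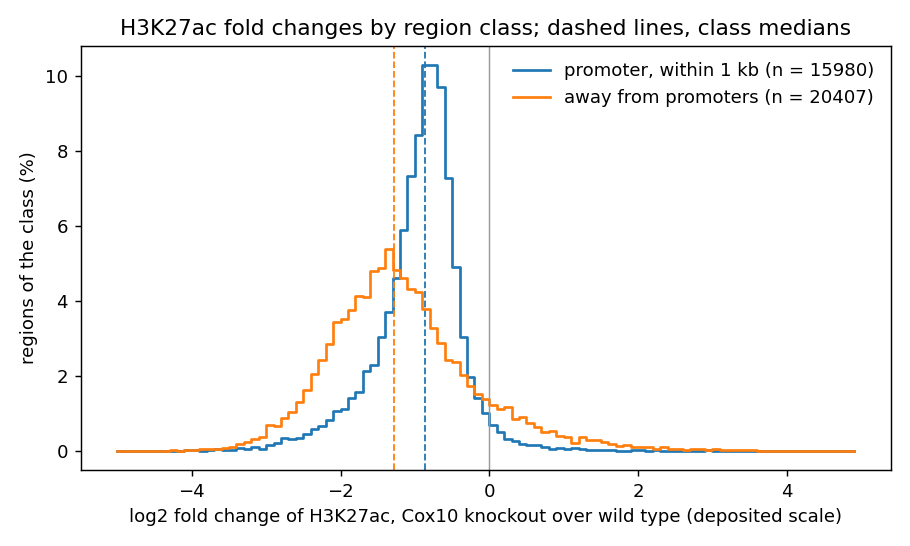
Distribution of log2 fold changes (knockout over wild type, deposited scale, x axis) as the percent of regions of each class (y axis), for 15980 promoter regions in blue and 20407 other regions in orange. Dashed lines mark the class medians of -0.87 and -1.28.

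Gene lists were tested at promoters to describe which parts of liver biology moved apart from the general shift. On the deposited scale 9073 of 9663 promoter genes were lower and 78 higher. List values below are therefore relative to the median level over promoter genes in each library. This centre lies slightly below the median change of promoter genes, which was -0.82 (log2) on the deposited scale. Complexes II, III and V, for example, had a centred median of 0.04 and a deposited median of -0.83. On centred values, 2301 of the 9663 genes were lower and 2554 higher. Counts of list members at promoters are to be read against these shares. Of 30 lists, 11 were lower than other genes and 6 higher (camera, adjusted p under 0.05). All 11 lower lists also passed with an estimated correlation, with adjusted p from 0.0132 to 0.0418, and of the higher lists 1 did. On the deposited scale the counts were 11 lower and 3 higher, with 10 lower and 2 higher lists called on both scales, and 0 and 0 under an estimated correlation.

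Lists of hepatocyte function were among the 11 lower ones. These lists share genes and do not count as separate results. Serpina1c, Pck1, Cps1 and Ass1 are in the periportal list and in another lower list, and Cyp2e1 and Nr1i3 likewise in the pericentral list. Hepatocyte secreted proteins had a median of -0.87, with 33 of 37 members lower, 1 higher and 3 not called (34 lower and 1 higher adjusted over the list alone, camera adjusted p = 4.6e-30). Serpina1c, another alpha-1-antitrypsin gene, was 12.1-fold lower on the deposited scale (log2 -3.60, SE 0.11), and Vtn, encoding vitronectin, 8.45-fold lower (log2 -3.08, SE 0.098). Among urea cycle and amino acid breakdown genes 26 of 27 were lower and 1 higher, the same counts adjusted over the list alone (median -0.84, adjusted p = 1.8e-23). This list includes Mat1a, the liver methionine adenosyltransferase, and Slc25a13, the mitochondrial aspartate-glutamate carrier, 4.28-fold and 4.52-fold lower on the deposited scale. Periportal genes had 17 of 21 lower and 2 higher (17 and 3 adjusted over the list alone, median -0.84, adjusted p = 3.4e-16), and pericentral genes 12 of 18 lower and 0 higher (13 and 0 adjusted over the list alone, median -0.62, adjusted p = 5.2e-06). Xenobiotic metabolism had 20 of 23 lower and 0 higher, the same adjusted over the list alone (median -0.83, adjusted p = 9.2e-11), including Cyp2e1 and Cyp2b9, 8.63-fold and 4.06-fold lower on the deposited scale.

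Transcription factors of hepatocytes were lower in 21 of 24 members and higher in 0, the same adjusted over the list alone (median -0.52, camera adjusted p = 7.8e-14). Nr1i3, the constitutive androstane receptor, was 4.97-fold lower on the deposited scale (log2 -2.31, SE 0.091), and Onecut2 was 3.61-fold lower. Acute phase genes, among them Hp (haptoglobin) and Itih4, were lower in 12 of 19 and higher in 2, the same adjusted over the list alone (median -0.57, adjusted p = 7.9e-08). Hp was 4.88-fold and Itih4 4.42-fold lower on the deposited scale.

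Metabolic lists divided. Gluconeogenesis was lower in 9 of 10 members and higher in 0, the same adjusted over the list alone (median -0.60, camera adjusted p = 7.4e-09), with Pck1, the cytosolic phosphoenolpyruvate carboxykinase, 7.02-fold and Fbp1 4.39-fold lower on the deposited scale. Bile acid synthesis and transport was lower in 15 of 17 and higher in 1, the same adjusted over the list alone (median -0.67, adjusted p = 1.9e-10). Slc10a1, the bile acid uptake transporter of hepatocytes, was 7.15-fold lower on the deposited scale. Fatty acid and triglyceride synthesis was lower in 12 of 19 and higher in 1, the same adjusted over the list alone (median -0.24, adjusted p = 0.00068), with Srebf1, a master regulator of lipid synthesis, 5.04-fold and Fasn 3.31-fold lower on the deposited scale. Several lists did not pass: cholesterol synthesis (median -0.10, adjusted p = 0.17), phospholipid synthesis (-0.07, adjusted p = 0.23), fatty acid oxidation with PPARalpha targets (-0.15, adjusted p = 0.71), glycolysis (-0.07, adjusted p = 0.86) and the TCA cycle (-0.04, adjusted p = 0.69). On the deposited scale phospholipid synthesis was lower (camera adjusted p = 0.0188), but not with an estimated correlation (adjusted p = 0.427). Fatty acid oxidation held members of both directions, 14 lower and 10 higher. In that list the promoter of Pdk4 was 2.40-fold higher on the deposited scale (log2 1.27, SE 0.10), while Fabp1 and Ppara were 3.27-fold and 2.98-fold lower.

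Lists of the respiratory chain had medians near that of all promoter genes. Complex I subunits had a median of 0.06 (31 genes, camera adjusted p = 0.86), complexes II, III and V 0.04 (24 genes, adjusted p = 0.78), and cytochrome c oxidase subunits and assembly factors, to which Cox10 belongs by function, 0.12 (24 genes, adjusted p = 0.59). For complex I the median lay above 0 and the mean just below it, at -0.0022. Mitochondrial ribosome and translation genes had a median of 0.06 (39 genes, adjusted p = 0.69), and histone acetylation enzymes one of -0.04 (24 genes, adjusted p = 0.59). On centred values 4 of 31 complex I genes were lower and 3 higher (2 and 3 adjusted over the list alone). Counts were 4 and 3 of 24 for complexes II, III and V (2 and 2), and 2 and 3 of 24 for cytochrome c oxidase (2 and 3). Members named by the smallest adjusted p fell further than their lists. On the deposited scale Ndufa8, Sdhd and Coa6 were 2.42-fold, 2.57-fold and 2.63-fold lower (log2 -1.28, -1.36 and -1.40, against list medians of -0.81, -0.83 and -0.74). Sirt3, the mitochondrial deacetylase, was 3.58-fold lower.

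The list of the ATF4 and mitochondrial stress response moved the other way. Of 29 ATF4 and mitochondrial stress genes, 23 were higher on centred values and 0 lower (23 higher and 1 lower adjusted over the list alone, median 0.64, camera adjusted p = 1.1e-11). This list call held with a camera adjusted p of 0.0132 under an estimated correlation. By contrast, 13 members were lower and 7 higher on the deposited scale (median -0.22). Among those 7, Trib3, a pseudokinase induced by ATF4, was 2.08-fold higher (105 ± 19.8 to 217 ± 29.7 normalised reads, SD, n = 3), and Nupr1 was 2.23-fold higher. Shmt2 and Hspe1 were 2.07-fold and 1.99-fold lower on that scale, and neither was called on centred values.

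Cell cycle and DNA replication genes were lower in 15 of 27 members and higher in 0, the same adjusted over the list alone (median -0.74, camera adjusted p = 0.00017; the deposited scale gives adjusted p = 0.107). Ccnd1, encoding cyclin D1, was 3.52-fold and Mcm10, a replication factor, 5.25-fold lower on the deposited scale. Immediate early and priming genes of regeneration were higher in 13 of 21 and lower in 3 (14 and 3 adjusted over the list alone, median 0.26, adjusted p = 0.0007, adjusted p = 0.106 with an estimated correlation). Myc was 1.28-fold higher on the deposited scale (log2 0.36, SE 0.078), and Il6ra, the interleukin 6 receptor, 2.81-fold lower. Targets of p53 were higher in 10 of 17 and lower in 3 (11 and 3 adjusted over the list alone, median 0.25, adjusted p = 0.0118, adjusted p = 0.0952 with an estimated correlation). NRF2 targets were higher in 10 of 18 and lower in 2 (11 and 2 adjusted over the list alone, median 0.24, adjusted p = 0.0118, adjusted p = 0.112 with an estimated correlation), with Nqo1 1.44-fold higher and Gsta2 3.16-fold lower on the deposited scale. HIF targets were higher in 7 of 19 and lower in 3, the same adjusted over the list alone (median 0.18, adjusted p = 0.0352, adjusted p = 0.141 with an estimated correlation). The direction of members in these 4 lists turned with the scale: on the deposited scale 17 immediate early genes were lower and 1 higher, 13 and 0 p53 targets, 15 and 1 NRF2 targets, and 17 and 0 HIF targets. None of the 4 lists was called on that scale, with adjusted p of 0.697, 0.113, 0.226 and 0.335.

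**Figure D3:**
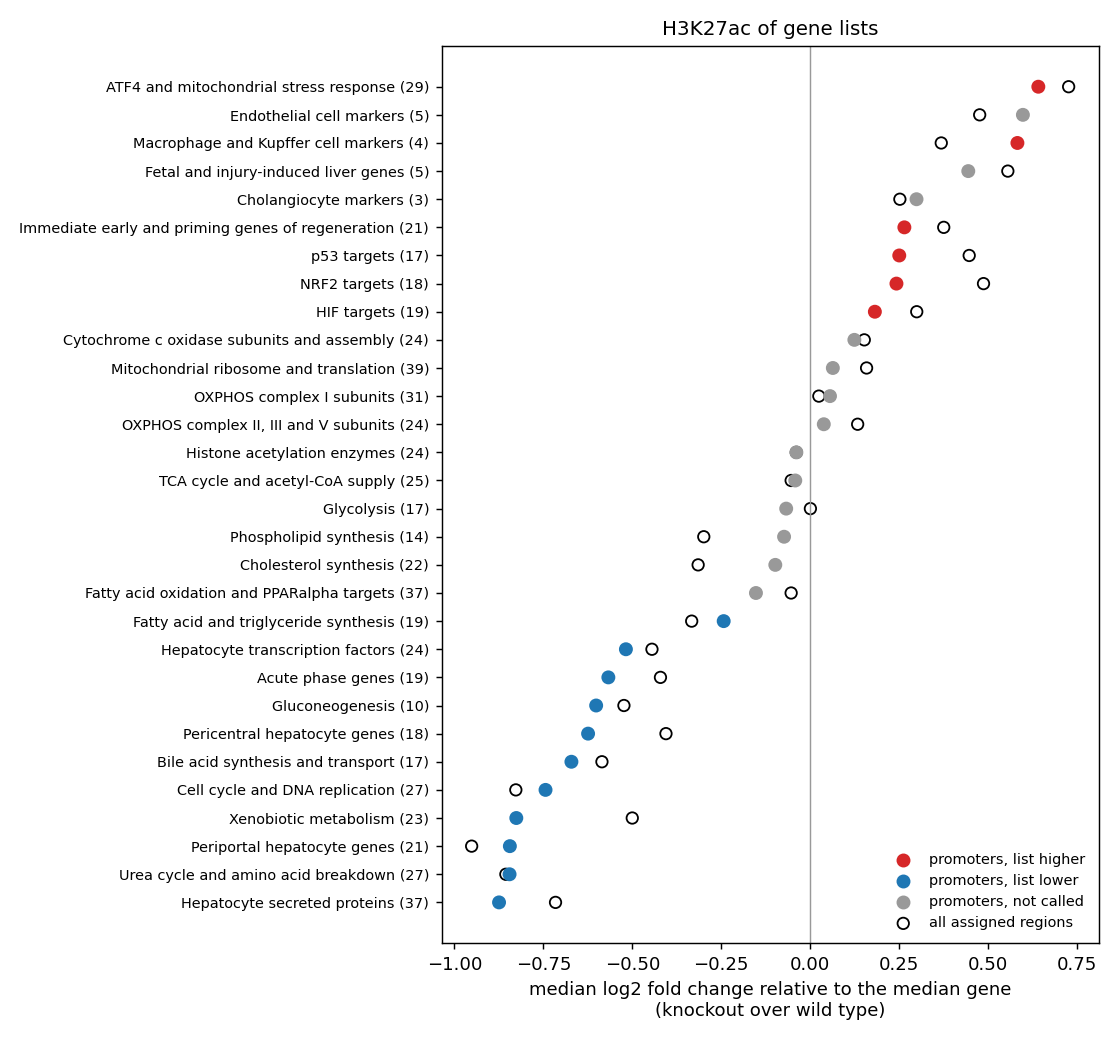
Median log2 fold change of gene lists relative to the median gene of each library (x axis; knockout over wild type), at promoters (filled; red, list higher; blue, list lower; gray, not called; number of genes in parentheses) and over all assigned regions (open). Among the 30 lists drawn, those with at least 3 promoter genes, the ATF4 and mitochondrial stress list lies highest at 0.64 and hepatocyte secreted proteins lowest at -0.87 at promoters.

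Over all regions assigned to a gene, 12 of 32 lists were lower and 3 higher (camera, adjusted p under 0.05), and the counts of members given here were the same adjusted over the list alone. The share of all 11240 genes called at this level was not counted, so these counts lack a background of genes. Of single regions in centred libraries, 32.4% were lower and 33.6% higher. The urea cycle list had a median of -0.86 (24 of 27 genes lower, 0 higher, adjusted p = 1.3e-08) and hepatocyte secreted proteins -0.72 (30 of 37 lower, 3 higher, adjusted p = 1.3e-08). Both held with an estimated correlation, at adjusted p = 0.0452 each. ATF4 and mitochondrial stress genes had a median of 0.73 (21 of 30 higher, 2 lower, adjusted p = 4.5e-05, adjusted p = 0.0714 with an estimated correlation). NRF2 targets had a median of 0.49 (13 of 19 higher, 2 lower, adjusted p = 0.0029, adjusted p = 0.0915 with an estimated correlation), and immediate early genes 0.38 (14 of 22 higher, 3 lower, adjusted p = 0.0126, adjusted p = 0.117 with an estimated correlation). Cholesterol synthesis was lower here (13 of 23 lower, 5 higher, median -0.31, adjusted p = 0.0274, adjusted p = 0.118 with an estimated correlation). The other 9 lower lists were also lower at promoters, and over all regions they had adjusted p from 0.0524 to 0.253 with an estimated correlation. On the deposited scale 6 lists were lower than other genes and 8 higher, of which 6 and 3 were called on both scales. Each of the 8 had more genes lower than higher in the knockout on that scale. For HIF targets these were 15 and 2 of 20 genes. With an estimated correlation that scale gave 0 lower and 0 higher.

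Markers of other cell types were examined because whole liver holds macrophages, endothelial, stellate, biliary and blood cells. At promoters 1 of 3 testable marker lists was higher than other genes, that of macrophages and Kupffer cells (3 of 4 genes higher, 1 lower, also adjusted over the list alone, median 0.58, camera adjusted p = 0.0285, adjusted p = 0.132 with an estimated correlation). Cd14, a lipopolysaccharide co-receptor, rose from 140 ± 1.26 to 314 ± 28.3 normalised reads (SD, n = 3; 2.22-fold), while Cx3cr1 was 2.35-fold lower on the deposited scale. This call ended with the mean over promoter regions (adjusted p = 0.082), and on the deposited scale 2 of the 4 genes were lower and 1 higher. Endothelial markers had a median of 0.60 in 5 genes (adjusted p = 0.176). On the deposited scale that list was higher than other genes (camera adjusted p = 0.0096), but not with an estimated correlation (adjusted p = 0.301). There 3 of its 5 genes were lower in the knockout and 0 higher, with a median of -0.27. The list thus fell less than other genes. Cholangiocyte markers had a median of 0.30 in 3 genes (adjusted p = 0.76). Fetal and injury-induced liver genes had a median of 0.44 in 5 genes (adjusted p = 0.104). Stellate and lymphoid markers had 2 and 1 genes with a promoter region and were not tested there. Over all assigned regions 0 of 5 marker lists passed, with medians of 0.37 for macrophages, 0.48 for endothelial cells, 0.57 for stellate cells, 0.25 for cholangiocytes and -0.37 for lymphocytes and neutrophils. On the deposited scale 2 marker lists were higher than other genes at promoters and 3 over all regions, and 0 at either level with an estimated correlation. Each of these lists had more genes lower than higher in the knockout on that scale.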

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

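Alternatives that use other scalings, recovered reads, centred or deposited values or bins of mean signal were chosen after seeing the data, as was the centred scale of the list test itself; the estimated correlation and fry were named before the data were examined, and their centred scale was not. With deposited size factors, edgeR gave 31769 regions lower and 1608 higher and DESeq2 30860 and 1299. The same regions on other scalings gave 12164 lower and 12145 higher with TMM (median -0.0019), 12098 and 12226 with median-of-ratios factors (0.0019), 12785 and 11293 with total reads in the regions (-0.041), and 11800 and 12224 when centred (0.012), since each sets the typical region near 0. A log2 fold change of at least 1 left 19025 and 724. A mean signal at or above the median left 17132 and 285, so higher calls dropped far more than lower ones. The promoter difference of 0.42 was 0.34 with a 3 kb window and 0.24, 0.36, 0.47 and 0.32 in bins 1, 2, 4 and 5 of rising mean signal; the cause was not tested. Centred odds ratios were 0.307 for lower and 1.98 for higher calls. Leaving out each library gave 31097 to 31688 regions lower, 1385 to 1648 higher, a median of -1.07 to -0.99, a Cox10 log2 fold change of 1.75 to 2.01, and 11 to 11 lists lower and 6 to 6 higher at promoters. Promoter lists higher were 5 with the mean over promoter regions, where macrophage markers lost their call (adjusted p = 0.082), 7 with a 3 kb window, where fetal and injury-induced genes gained one (adjusted p = 0.023), 1 with an estimated correlation, 3 on the deposited scale, and 0 (with 0 lower) on the deposited scale with an estimated correlation. Fry, which does not compare a list with other genes, gave 15 lower and 9 higher. Over all regions, lists numbered 5 higher with the region of highest signal, 2 lower and 0 higher with an estimated correlation, 6 lower and 8 higher on the deposited scale, and 0 and 0 on that scale with an estimated correlation. Marker lists higher were 0 over all regions, 0 with an estimated correlation and 2 on the deposited scale; the cause was not tested. Of 64 list genes named by the rule, 52 kept direction and call when centred and 4 lost the call; 8 turned positive: Peg3 0.052, Mybl1 0.22, Fcer1g 0.39, Fli1 0.60, Gpr182 0.26, Vim 0.47, Slc4a2 0.30 and Lck 0.54. Fli1 lost its call without wild-type replicate 2 (-0.20) or 3 (-0.21), Gpr182 without wild-type replicate 2 (-0.43) or knockout replicate 3 (-0.53), and Vim without wild-type replicate 3 (-0.29). Replicate numbers did not pair the libraries (correlations of deviations -0.001, 0.007 and 0.005); with the replicate number as a block, 31755 regions were lower and 1634 higher, and 11 and 5 promoter lists, macrophage markers losing their call (adjusted p = 0.064). A low-count filter in edgeR removed 2 regions and gave 31767 lower and 1608 higher. The limit of 50 kb around start sites was not run. In simulated data at the depth and number of these libraries, with few regions changed and no common shift, 54% of 1.5-fold changes were recovered. Recovery in the data may differ, and other depths were not simulated.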

Other observations

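Genes with several regions of the same direction were counted after the data were examined, on the deposited scale. Of 2203 genes with at least 5 regions, 9 had at least 80% of them higher in the knockout. All 5 regions nearest to Src, the tyrosine kinase, were higher (mean log2 1.57), as were all 7 nearest to AU019990 and 10 of 12 nearest to Dlgap1 (1.06, with 1 lower). Gab2, an adaptor of receptor signalling, had 5 of 6 higher (1.19) and Hilpda, a lipid droplet protein induced by hypoxia, 4 of 5 (0.83). In the other direction 42 genes had a mean under -2.5. They include Serpina1c (6 of 6 regions lower, mean -3.47) and Serpina1e (6 of 6, -3.21), whose reads may be shared between copies, Mycn (5 of 5, -3.06), Haao of tryptophan breakdown (10 of 10, -3.05), Nags of the urea cycle (6 of 6, -2.69) and Khk, ketohexokinase (5 of 5, -2.68).

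The tests below on the size factors, the common factor, the shared pool and the share of hepatocytes were chosen after the results they measure were seen. The median region was 2.06-fold lower in the knockout on the deposited scale. The differences between regions are more than 1 common factor gives, since fold changes spread 5.30 times as widely (SD 0.848) as the median standard error of a region (0.160), but this spread says nothing about the shift of the median. The size factors stay open as a cause. The median was -0.33 in recovered reads before any scaling, but these mix the depth of each library, whose total sequenced reads were not used here, with any loss of H3K27ac. Scaling to total reads in the regions (-0.041) removes a global change by construction. A global loss of H3K27ac and a scaling difference therefore cannot be told apart without the spike-in reads, which were not used here. Calls were 33341 regions for the genotypes and 0 for the highest of the other splits. Every other split mixes the genotypes, so their difference widens the spread within its groups, and the 0 is not a level of noise. Only 1 of the 10 splits reached the real count, the real one itself, and 10 splits are too few for a share under 0.05.

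Libraries of a genotype differed by little more than sampling noise. The highest chi-square per degree of freedom of a pair of the same genotype was 1.19, which is consistent with libraries drawn from a shared pool of chromatin or with very uniform animals. The labels do not say which, and no biological explanation was tested. If the libraries share a pool, the p-values given for regions and lists do not measure variation between animals.

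On centred values over all assigned regions, hepatocyte genes were lower and markers of other cell types tended higher. Of 32 marker genes, 23 lay above the centre of the libraries, with a median of 0.40. The median gene itself lay slightly above this centre. The 23 therefore include Dcn (0.060), which lay no higher than the median gene. Low signal at these regions is argued against as the whole cause, since 10000 random lists matched on mean signal had a median of -0.08 and an upper limit of 0.19. A lower share of hepatocytes stays open: a permutation test between the marker lists (p = 0.23, 100000 permutations) decides nothing, because the smallest list held 4 genes, fewer than the 5 it needed. Such a share cannot be told apart from lower H3K27ac within hepatocytes. Lists called numbered 17 at promoters for the genotypes against 14 for the highest other split, and 15 over all regions against 12; in each case 1 of the 10 splits, the real one, reached that count, and 10 splits are too few for a share under 0.05. The genotypes gave 14 promoter lists on the deposited scale, and the highest other split 16. The other splits still mix the genotypes unequally.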
